A study of Mus musculus with 2084 samples.

How the data were processed

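RNA was measured in single cells of the adult mouse vSVZ, striatum, cortex and olfactory bulb, as the transcriptome part of a combined transcriptome and epigenome assay; the epigenome was not analysed here. Per the labels' protocols, TiCY mice received tamoxifen, which activates eYFP in neural stem cells that express Tlx, and some then had both carotid arteries occluded 2 weeks later and were killed 2 d or 21 d after that. WT mice had neither tamoxifen nor ischemia. Cells were sorted with antibodies that included GLAST, O4, PSA-NCAM, Prominin1, CD9, CD45 and Ter119, from individual or pooled mice, and libraries were made by Smart-seq3. Each labelled sample is 1 cell. The letter at the end of a cell's name (pA to pM) was taken as its biological replicate of 1 or more mice. A p-value of a single gene thus measures spread between letters. The striatal 2 d fit is the exception, as its spread came from the trend over genes. A p-value of a gene list (camera) sets its members against the other genes and does not measure that spread.

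Per the labels, the authors aligned reads with STAR and counted them per gene with featureCounts on GRCm38 (mm10), and the deposited values are raw counts per gene and cell. Versions, annotation and filters on cells are not given in the sources used here. The values were checked to be whole numbers, and they looked like counts of reads rather than of molecules. The main table held 2584 cells and 35606 gene identifiers, of which 35455 had a symbol in GENCODE M21; 47 identifiers share a symbol with another. Of its cells, 1981 matched a labelled cell and 603 matched none and were not used. The labels held 2084 cells in 37 groups and 11 letters. A second table of 614 ischemia cells shared 513 with the main table, and 87 marker genes compared in both were 100% equal; its other 101 cells were not used in any comparison, and 2 labelled oligodendrocytes matched neither table. No pair of cells had identical counts. Gene coordinates are those of GENCODE M21 on GRCm38, 1-based. Of 72 genes named with a comparison, 14 overlap another gene on the same strand, among them Mcm7, Slc1a3, Gsn, Gli3, Nrxn3, Ifnar2, Anxa2, Cit and Top2a, and 35 overlap a gene on either strand, so some of their reads may have been assigned either way.

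Cells held 3771 to 1842234 counts (median 160621) over 1534 to 10660 genes (median 4994). Median depth per letter was 648839 in pA, 1000343 in pB, 153382.5 in pC, 120498 in pD, 845587 in pE, 145147 in pF, 160858.5 in pH, 304367 in pI, 155357 in pL and 151508 in pM. In pJ it was 164287 for naive cells and 110133 for 2 d cells. Letters formed 3 library sets. In pA, pB and pE mt-Co1 took 1.70% to 2.93% of counts, in pC, pD and pF Olfr905 took 1.599% to 2.604%, and in the others Malat1 had counts. Between pA to pF and pH to pM, 121 genes at 50 CPM or more in the latter had 0 counts in the former and 2 the reverse, so the counting annotation may have differed. Tests of WT cells and the bulb comparison therefore stayed within pA to pF.

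Counts were summed over the cells of a type or sort in a letter. Sums of under 3 cells were left out, which removed qNSC2 of pC, aNSC of pA and pB, and TAP of pB. WT types made 22 sums in 1 fit (14915 genes, 16 residual degrees of freedom, prior 6.22). The sums held 13, 11, 17, 57 and 20 cells for qNSC1 (pA to pE), 3, 3, 34 and 9 for qNSC2 (pA, pB, pD, pE), 10, 63 and 3 for aNSC (pC, pD, pE), 12, 71 and 3 for TAP (same letters), 20, 25, 27 and 7 for neuroblasts (pA to pD) and 9, 24 and 25 for oligodendrocytes (pA to pC). Sorts of pA, pB and pC made 12 sums (14348 genes, 8 residual degrees of freedom, prior 4.57), naive pM and pJ 12 sums (16009 genes, 6 and 6.85), and striatal sorts 5 sums (22409 genes, 1 residual degree of freedom, infinite prior), the last with terms for genotype and time. Tests used edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test) with Benjamini-Hochberg adjustment at 0.05, in R 4.3.3 with limma 3.58.1; CPM of tested genes are TMM-normalised. Lists were tested with camera at a correlation of 0.01 and again with an estimated correlation, and by adjusting p over the list alone. Types in the labels may rest on these transcriptomes, so p-values between types are descriptive; the surface sorts do not rest on them.

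Letters were checked for pairing by correlating the deviations of sums from their group means. Between qNSC1 and qNSC2, 4 shared letters gave 0.149 to 0.527 and different letters a median of -0.0948. In every comparison each same-letter pair was above 0.1. Types of 1 letter may share mice, a sort or a plate, which the sources used here do not part. Letter pJ holds both naive and post-ischemia cells. The fit with the letter as a block was therefore given where it changed a call or moved a count more than 1.5 times.

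Groups of 1 letter were compared without a test. Summed counts were scaled to CPM with exact 95% Poisson intervals, and ratios were log2 of the CPM with 5 added to each. List medians used members with a mean of 5 CPM or more over the 2 groups. They carry counting intervals from 1000 Poisson draws and a percentile among 10000 random lists matched on mean expression in 40 bins. Folds against 0 counts were computed against a floor of 3 counts over the group and are lower bounds. The bulb was compared with each of pA to pD and with their mean. GLAST-sorted cells of the vSVZ and striatum in TiCY and KO mice (1362) were scaled to their median total of 160381.5, log transformed and clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 20 components, 15 neighbours, resolution 1), and clusters were named from marker scores; shares carry exact binomial intervals. Cells were also thinned to 50000 counts. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

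Lists were fixed before the data were examined, as were the comparisons, the rule for naming genes and most alternatives; the rule for naming clusters was set after a first clustering had been seen. The 26 lists were astrocyte, quiescent NSC, activated NSC and TAP, proliferation, neuroblast, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, pericyte and vascular smooth muscle, ependymal, mature neuron, reactive astrocyte, interferon response, interferon receptors, immediate early and stress, ribosomal protein, cholesterol synthesis, fatty acid oxidation, glycolysis, oxidative phosphorylation, hypoxia response, DNA methylation machinery, Wnt target, Notch pathway and forebrain patterning. Genes were named by rule. In tests they were the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 20 CPM that moved the same way in every letter with both groups, without predicted genes and pseudogenes, and up to 4 members per list with the smallest p. Without a test they were the 8 highest and 8 lowest ratios with at least 50 CPM in the higher group, counts in at least 20% and 5 of its cells, and the same direction at least 2-fold with equal weight per cell, and up to 4 members per list with the highest mean CPM. The text gives a selection of these, and the interferon receptors were examined in every KO comparison.

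Alternatives were DESeq2 1.42.0, no filter on genes, equal weight of cells with limma trend, the letter as a block, each letter left out, only the groups compared, other minimums of cells per sum (5 and 1), naive pM and pJ in place of WT, other priors (1 and 20 CPM), equal weight of cells in ratios, a minimum of 1000 genes per cell, other clustering resolutions (0.5 and 2) and another seed. Fits within a library set or with it as a block, genes detected in at least 20% of cells, and ratios without the 5% of cells with each gene's highest shares were chosen after the data were seen.

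The tests were tested on simulated data drawn from the real means and depths, with genes changed 4-, 16- or 64-fold. Between qNSC2 and qNSC1 the fit recovered 2.99%, 31.3% and 66.7% of these, in the same order of folds, between TAP and aNSC 0%, 8.96% and 42.4%, between the NB and NSC sorts 0%, 31.3% and 60.6%, between qNSC2 and vSVZ astrocytes 0%, 19.4% and 40.9%, between striatal and vSVZ astrocytes 0%, 13.4% and 36.4%, and for 2 d against naive in the striatal sort 1.49%, 31.3% and 59.1%. Differences of 4-fold were thus mostly out of reach of the tests on these sums. Poisson intervals covered 97.1% and ratio intervals 96.6% of simulated values.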

Results

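RNA was counted per gene in single cells of the adult mouse neural stem cell (NSC) lineage, together with astrocytes and oligodendrocytes sorted from the ventricular-subventricular zone (vSVZ), striatum, cortex and olfactory bulb. Of 2084 labelled cells, 1981 were used. They carried 11 letters, each taken as 1 replicate. Letter pJ holds both naive and post-ischemia cells, so a letter need not be 1 set of mice. A cell held a median of 160621 counts over 4994 genes. Wild-type (WT) naive cells came from replicates pA to pF. TiCY cells, in which tamoxifen switches on eYFP in cells that express Tlx, came from pH, pI and pM, and WT cells with a TCF-Lef reporter from pL. Interferon receptor knockout (KO) cells came from pJ; the labels put those taken 2 d after ischemia on the TiCY background and leave the background of the naive ones open. WT types were compared on counts summed over the cells of a type in a replicate, so each edgeR p-value of a gene there measures spread between replicates. Camera p-values set the genes of a list against the other genes and do not measure that spread. TiCY and KO arms mostly held 1 replicate each, and their values carry exact Poisson intervals in square brackets, which cover counting error alone.

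Genes lower in cells labelled qNSC2 than in cells labelled qNSC1, both labels of quiescent NSCs, included Il33, Kcnj16 and Slc1a4. Il33, an alarmin of astrocytes and oligodendrocytes, averaged 130 ± 67.2 CPM (mean ± SD, 5 replicates) in qNSC1 and 0 in 4 replicates of qNSC2, a fall of at least 642-fold (edgeR adjusted p = 0.0024, lower in 4 of 4 replicates). Kcnj16, a subunit of the potassium channel that buffers potassium around synapses, fell from 91.2 ± 46.6 to 0.506 ± 0.229 CPM (log2 fold change -7.47 ± 1.16 SE, edgeR adjusted p = 0.0087, lower in 4 of 4). Slc1a4, which exports serine to neurons, fell from 333 ± 126 to 36.6 ± 11.02 CPM (-3.18 ± 0.61, edgeR adjusted p = 0.041, lower in 4 of 4). Gng2, a G protein subunit at 14:19872559-19977627, rose from 1.28 ± 0.924 to 82.0 ± 68.0 CPM (5.96 ± 0.82, edgeR adjusted p = 0.0024, higher in 4 of 4). Tshr, the thyrotropin receptor at 12:91384563-91549808, rose from 0.20 ± 0.183 to 60.1 ± 48.9 CPM (7.94 ± 1.36, edgeR adjusted p = 0.038, higher in 4 of 4), with 44.8% of its counts in 1 cell. In all, edgeR called 12 of 14915 genes, 5 higher and 7 lower; with the replicate as a block it called 60, 16 higher and 44 lower, within replicates pA, pB and pE alone 22, within pC and pD alone 0, and without pA or pB 0.

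Of the gene lists between qNSC1 and qNSC2, none held with an estimated correlation (lowest 0.0692). All 18 astrocyte genes lay lower in qNSC2 (median log2 fold change -1.69, camera adjusted p = 9.3e-07, and 0.138 with an estimated correlation). Reactive astrocyte genes leaned the other way, 12 of 16 higher (median 2.41, camera adjusted p = 0.00022, and 0.0692 with an estimated correlation), and 7 rose while 1 fell when adjusted over the list alone. Ependymal genes lay higher for 6 of 9 (median 2.71, camera adjusted p = 0.00014, 0.138 estimated), a list of genes of ciliated ventricle cells. Oligodendrocyte genes lay lower for 15 of 16 (-2.81, camera adjusted p = 0.00071, 0.346 estimated) and precursor genes for 8 of 8 (-2.08, camera adjusted p = 0.013, 0.126 estimated), Olig1 among them (22.6 ± 12.04 to 0.0386 ± 0.0772 CPM, edgeR adjusted p = 0.041, -8.15 ± 1.54, lower in 4 of 4). Quiescent NSC genes had a median of 0.39 (11 of 18 higher, camera adjusted p = 0.0029, 0.334 estimated), immediate early genes 1.84 (13 of 18, 0.013 by camera, 0.543 estimated) and ribosomal protein genes 0.39 (26 of 30, 0.0036 by camera, 0.764 estimated). Glycolysis genes lay lower for 15 of 17 (-0.95, camera adjusted p = 0.0027, 0.138 estimated) and cholesterol synthesis genes for 14 of 17 (-0.54, camera adjusted p = 0.03, 0.431 estimated).

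Camera called none of the other lists between qNSC2 and qNSC1. Their medians were -2.58 for 3 microglia genes (camera adjusted p = 0.733), -0.84 for 3 endothelial genes (0.844), -1.34 for 8 mature neuron genes (0.503), 0.37 for 15 activated NSC and TAP genes (0.288), 0.48 for 20 proliferation genes (0.206), 0.33 for 20 neuroblast genes (0.168) and -0.52 for 19 fatty acid oxidation genes (0.151). The 4 interferon receptors had a median of -0.57 (camera adjusted p = 0.206), 13 hypoxia genes 0.33 (0.948), 12 Wnt targets 0.16 (0.118) and 12 forebrain patterning genes -0.49 (0.948). Oxidative phosphorylation had a median of -0.33 over 21 genes (camera adjusted p = 0.288, and 0.0232 with the replicate as a block). Median, mean and test differed in sign for 4 lists: pericyte genes (median 0.10, mean -0.44), interferon response (-0.31 and 0.04), DNA methylation machinery (0.09 and 0.10, tested lower) and Notch pathway (-0.36 and 0.05).

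From qNSC2 to aNSC the replication genes Mcm7, Hells and Atad5 rose, and Thbs4, Gsn and Slc7a10 fell. Mcm7, part of the helicase that opens replication origins (5:138164583-138172422), rose from 9.76 ± 6.998 CPM in 4 replicates of qNSC2 to 328 ± 335 CPM in 3 replicates of aNSC (log2 fold change 5.06 ± 0.88, edgeR adjusted p = 0.027, higher in 2 of 2 replicates that held both). Hells, a chromatin remodeler needed to maintain DNA methylation, rose from 11.9 ± 6.52 to 279 ± 161 CPM (4.54 ± 0.91, edgeR adjusted p = 0.04, higher in 2 of 2), and the replication clamp unloader Atad5 rose from 2.83 ± 2.79 to 172 ± 162 CPM (5.92 ± 1.12, 0.027, 2 of 2). Thbs4, a matrix protein of quiescent NSCs (13:92751590-92794818), fell from 485 ± 113 to 10.4 ± 2.80 CPM (-5.54 ± 1.02, edgeR adjusted p = 0.027, lower in 2 of 2). Gsn, an actin-severing protein, fell from 175 ± 122 to 0.212 ± 0.368 CPM (-10.56 ± 1.46, edgeR adjusted p = 0.0043, lower in 2 of 2), and Slc7a10, a serine carrier of astrocytes, fell from 93.1 ± 86.1 to 0.979 ± 0.534 CPM (-6.52 ± 1.21, 0.027, 2 of 2). Olig1 rose from 0.0386 to 24.6 ± 32.1 CPM (8.29 ± 1.58, edgeR adjusted p = 0.027, higher in 2 of 2). In all, edgeR called 29 genes, 9 higher and 20 lower; with the replicate as a block it called 312, 175 higher and 137 lower. It called 0 without pC or pE or within pC and pD alone, 1 without pA or pB, and 320 within pA, pB and pE, where aNSC was 1 sum of 3 cells.

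Proliferation genes lay higher in aNSC for 20 of 20 (median 2.87, camera adjusted p = 3.7e-11, and 0.11 with an estimated correlation), 9 of them called over the list alone. Activated NSC and TAP genes lay higher for 14 of 15 (2.43, camera adjusted p = 8.2e-07, 0.0374 estimated) and ribosomal protein genes for 30 of 30 (2.19, camera adjusted p = 9.6e-16, 0.247 estimated). DNA methylation machinery lay higher for 10 of 17 (0.88, camera adjusted p = 0.0085, 0.0489 estimated). Fatty acid oxidation genes lay lower for 16 of 19 (-0.62, camera adjusted p = 0.0024, 0.0374 estimated), astrocyte genes for 18 of 18 (-2.42, 8.5e-08, 0.104 estimated), and quiescent NSC genes had a median of -1.44 (camera adjusted p = 0.00043, 0.224 estimated).

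Transit-amplifying progenitors (TAP) had higher neuroblast genes than aNSC as a list, while no single gene passed edgeR. The genes named here were chosen after their values were seen. Dcx, which bundles microtubules in migrating neuroblasts (X:143855842-143933311), averaged 287 CPM in TAP and 1.78 in aNSC (7.15 ± 1.58, edgeR adjusted p = 0.302, and 0.0372 with the replicate as a block). Sp8, a factor of dorsal interneurons, averaged 80.3 against 0.212 CPM (9.36 ± 1.97, edgeR adjusted p = 0.196, and 0.0479 with the block). Neuroblast genes lay higher in TAP for 20 of 20 (median 4.03, camera adjusted p = 1.5e-22, and 0.0063 with an estimated correlation), 13 of them called over the list alone. Astrocyte genes lay lower for 17 of 18 (-2.46, camera adjusted p = 1.1e-12, 0.0154 estimated), Notch genes for 12 of 14 (-2.23, 6.9e-05, 0.0063 estimated) and fatty acid oxidation genes for 18 of 19 (-0.74, 0.00015, 0.0063 estimated). Proliferation genes lay higher for 18 of 20 (1.63, camera adjusted p = 4.1e-06, 0.243 estimated). edgeR called 0 genes here against 937 with unadjusted p below 0.05; DESeq2 called 171, limma with equal weights 9, and edgeR with the block 18.

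**Figure D1:**
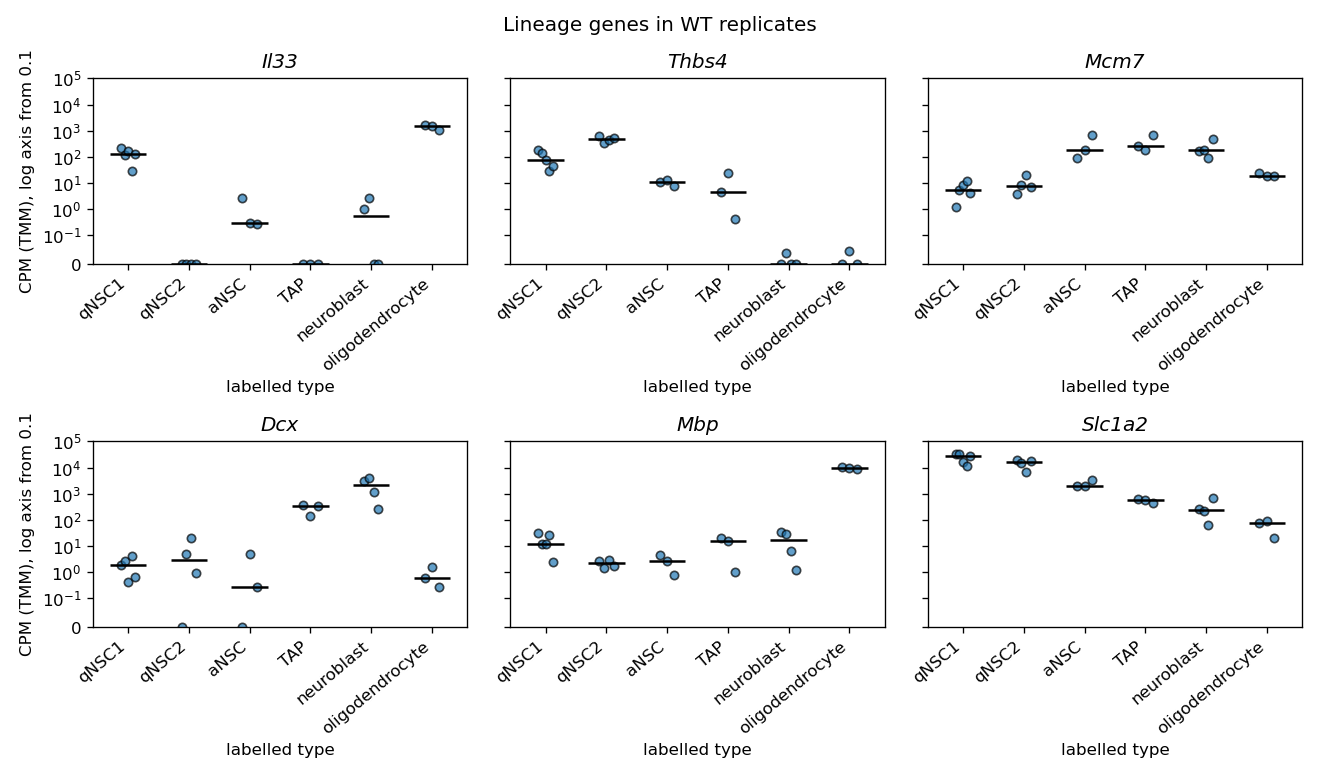
Expression of 6 lineage genes in WT types, in TMM-normalised CPM on a log axis (y) by labelled type (x). Each point is 1 replicate, such as 485 CPM on average for Thbs4 in qNSC2, and bars mark medians.

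From TAP to neuroblasts some stem cell genes fell, and proliferation genes lay lower as a list. Thbs4 fell from 9.25 ± 12.1 CPM in 3 replicates of TAP to 0.00987 ± 0.0197 in 4 of neuroblasts (-8.00 ± 1.21, edgeR adjusted p = 0.0041, lower in 2 of 2 replicates with both). Csrnp3, a neuronal transcription factor (2:65845767-66031546), rose from 0.477 ± 0.509 to 73.7 ± 49.9 CPM (7.05 ± 1.38, edgeR adjusted p = 0.043, and 0.058 with the block, higher in 2 of 2). Of the other 12 called genes, chosen after their values were seen, the receptor kinase Axl fell to 0.00987 from 13.05 CPM (-8.49 ± 1.00, edgeR adjusted p = 0.00031, lower in 2 of 2), and the hedgehog effector Gli3 to 0.36 from 24.1 CPM (-8.00 ± 1.56, edgeR adjusted p = 0.043, lower in 2 of 2). Proliferation genes lay lower for 20 of 20 (median -1.996, camera adjusted p = 1.2e-06, and 0.251 with an estimated correlation), ribosomal protein genes for 30 of 30 (-0.71, camera adjusted p = 0.00046, 0.517 estimated) and interferon response genes for 26 of 30 (-1.55, camera adjusted p = 0.0023, 0.326 estimated). Neuroblast genes lay higher for 17 of 20 (1.24, camera adjusted p = 0.00011, 0.251 estimated). Oligodendrocyte genes, which mark another lineage, also lay higher for 12 of 16 (1.94, camera adjusted p = 0.00036, 0.279 estimated, and 0.146 with the block). edgeR called 14 genes, 2 higher and 12 lower, and 0 without pB or within pC and pD alone. The balance depended on the tool: DESeq2 split its 309 into 153 higher and 156 lower, and limma with equal weights its 69 into 50 higher and 19 lower.

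Oligodendrocytes stood apart from qNSC1 by the myelin program. Mbp, the myelin basic protein (18:82475146-82585637), averaged 9613 ± 884 CPM in 3 replicates of oligodendrocytes and 16.9 ± 11.8 in 5 of qNSC1 (9.15 ± 1.06, edgeR adjusted p = 7.2e-06, higher in 3 of 3). Sox10, the master factor of the lineage, averaged 211 ± 30.8 against 0.0899 CPM (10.73 ± 1.05, edgeR adjusted p = 1.2e-05, higher in 3 of 3). The glutamate transporter Slc1a2 (2:102658659-102790784) fell from 24217 ± 9925 to 60.7 ± 36.3 CPM (-8.64 ± 0.99, edgeR adjusted p = 6.6e-06, lower in 3 of 3). Acsl6, which activates long-chain fatty acids, fell from 1351 ± 324 to 0.773 ± 0.473 CPM (-10.70 ± 1.04, edgeR adjusted p = 9.1e-07, lower in 3 of 3). Ndrg1, listed as a hypoxia gene but also a myelin gene, rose from 1.17 to 1644 ± 169 CPM (10.50 ± 1.55, edgeR adjusted p = 9.2e-05, higher in 3 of 3). edgeR called 1636 genes, 655 higher and 981 lower. Within pA, pB and pE alone it called 1471. Fewer were called without pA (885), without pB (847) or without pC (800). Called genes held all 16 oligodendrocyte genes (camera adjusted p = 0.00036 with an estimated correlation, median 10.15), 15 lower of 18 astrocyte genes (0.00099), 9 lower and 1 higher of 14 Notch genes (0.00099), 8 lower of 12 forebrain patterning genes (8.3e-05) and 6 lower of 19 fatty acid oxidation genes (0.0012).

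Surface sorts, which do not rest on the transcriptome, were compared with the NSC sort, itself a mix of labelled types, in 3 replicates. In the neuroblast (NB) sort Dcx averaged 2915 ± 1612 CPM against 1.62 ± 1.03 in the NSC sort (10.71 ± 1.17, edgeR adjusted p = 0.00024, higher in 3 of 3). Nrxn3, a synaptic adhesion gene, rose from 6.08 ± 1.57 to 957 ± 149 CPM (7.28 ± 0.64, edgeR adjusted p = 0.00014, higher in 3 of 3). Slc1a3, the GLAST antigen used for sorting, fell from 5621 ± 1829 to 21.7 ± 7.60 CPM (-8.02 ± 0.74, edgeR adjusted p = 0.00014, lower in 3 of 3), and Acsl3 from 1274 to 39.03 CPM (-5.03, edgeR adjusted p = 0.001, lower in 3 of 3). Ifngr1, the interferon gamma receptor, fell from 46.5 to 6.68 CPM (-2.79, edgeR adjusted p = 0.012, lower in 3 of 3). edgeR called 1690 genes, 519 higher and 1171 lower, more with the block (2755) and far fewer without pA or pB. The 1690 genes held 18 of 20 neuroblast genes (median 6.56, camera adjusted p = 0.0176 with an estimated correlation), 18 of 18 astrocyte genes (0.0171), 10 of 19 fatty acid oxidation genes (0.0176) and 9 of 17 glycolysis genes (0.0434), the last 3 lists all lower.

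In the OLIGO sort the called genes were mostly losses from the NSC sort. Gja1, the astrocyte gap junction protein, fell from 4687 to 2.37 CPM (-10.89 ± 0.87, edgeR adjusted p = 4.7e-05, lower in 3 of 3), and Egfr, which drives NSC activation, from 165 to 2.21 CPM (-6.18, edgeR adjusted p = 0.00049, lower in 3 of 3). Jam3, an adhesion gene of oligodendrocytes, rose from 51.2 ± 34.9 to 343 ± 22.2 CPM (2.74 ± 0.60, edgeR adjusted p = 0.015, higher in 3 of 3). edgeR called 875 genes, 34 higher and 841 lower; DESeq2 split its 1883 into 363 and 1520. Of genes called higher, 0 were left without pA, 23 without pB and 2 without pC, Jam3 in none of these fits, and the block called 216. Of 16 oligodendrocyte genes all lay higher but none was called (median 2.59, camera adjusted p = 0.193 with an estimated correlation), and the NSC sort itself held oligodendrocyte-labelled cells, 1 in pA and 7 in pB. Forebrain patterning genes fell for 8 of 13 (camera adjusted p = 0.0019 with an estimated correlation) and astrocyte genes for 16 of 18 (0.0059).

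The ASTRO sort had higher counts of neuroblast genes than the NSC sort. All 13 called genes were higher, among them Dcx (532 ± 521 against 1.62 ± 1.03 CPM, 8.25 ± 1.07, edgeR adjusted p = 0.019, higher in 3 of 3) and Stmn2, a microtubule regulator of growth cones (396 ± 452 against 0.499 CPM, 9.42 ± 1.41, edgeR adjusted p = 0.029, higher in 3 of 3). Nsg2, a neuronal endosome gene, rose from 0.834 to 120 ± 81.7 CPM (7.22 ± 0.89, edgeR adjusted p = 0.017, higher in 3 of 3). Neuroblast genes lay higher for 20 of 20 (median 4.39, camera adjusted p = 7.8e-42, and 0.0154 with an estimated correlation). Oligodendrocyte genes lay lower for 16 of 16 (-7.87, camera adjusted p = 1.1e-22, 0.14 estimated), with all 16 called over the list alone. The ASTRO sort contained neuroblast-labelled cells in each replicate (1 in pA, 4 in pB and 5 in pC), so the sort was a mix of types. With the block edgeR called 38 genes, 26 higher and 12 lower, and DESeq2 called 230 higher and 237 lower. edgeR called 0 without pA, without pB or with only the 2 groups in the fit, and 12 higher and 61 lower without pC.

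**Figure D2:**
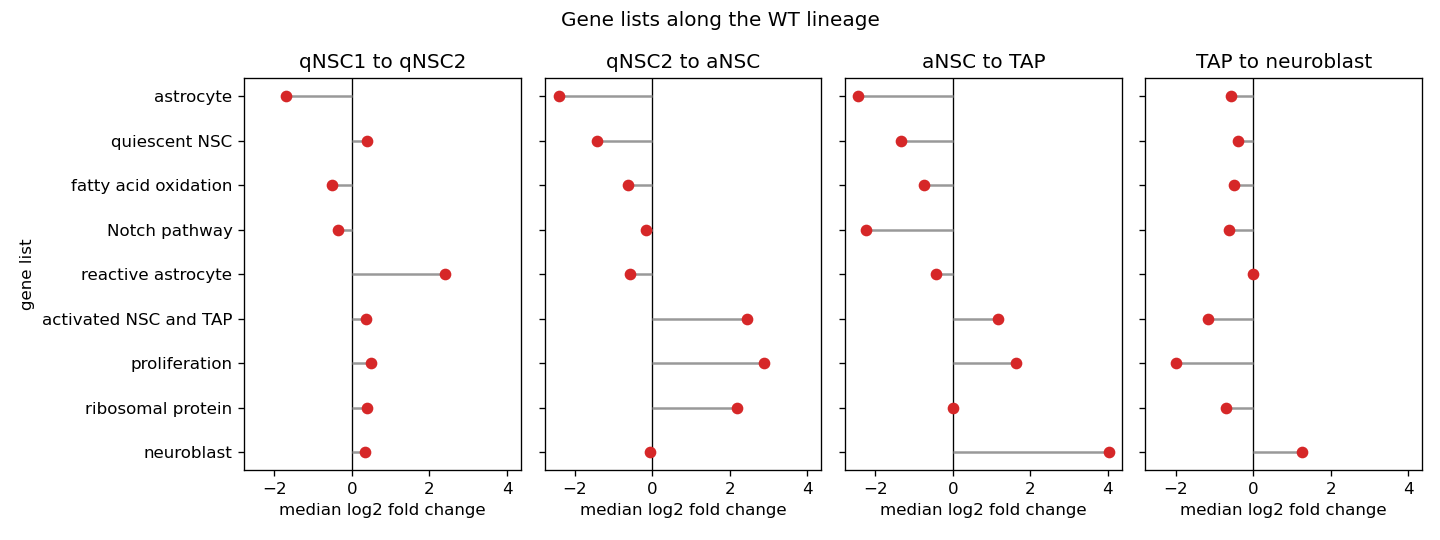
Median log2 fold change (x) of 9 gene lists (y) over 4 steps of the WT lineage, 1 panel per step. Each point is the median of the tested members of a list, such as 4.03 for neuroblast genes from aNSC to TAP, and the line at 0 marks no change.

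In naive TiCY and KO mice, stem cells labelled qNSC2 carried more of the G1 cyclin Ccnd2 than vSVZ astrocytes. Ccnd2 (6:127125162-127152193) averaged 840 ± 170 CPM in 2 replicates against 137 ± 4.19 (2.62 ± 0.32, edgeR adjusted p = 0.021, higher in 2 of 2), and the adhesion gene Dscaml1 averaged 42.0 ± 19.2 against 0.15 CPM (7.87 ± 0.99, edgeR adjusted p = 0.021, higher in 2 of 2). These were the 2 genes of 16009 that edgeR called; 640 had unadjusted p below 0.05, and DESeq2 called 107, 57 higher and 50 lower. With only these groups in the fit edgeR called 12 others and neither of this pair, and limma with equal weights did not call Dscaml1. Immediate early genes lay higher for 16 of 17 (median 3.82, camera adjusted p = 2.3e-10, and 0.147 with an estimated correlation), and astrocyte genes lower for 17 of 18 (-1.52, camera adjusted p = 1.4e-12, 0.105 estimated). Between striatal and vSVZ astrocytes edgeR called 0 of 16009 genes, 141 had unadjusted p below 0.05, and DESeq2 called 9; in simulated data this fit recovered 0% of 4-fold and 36.4% of 64-fold changes, so the count does not measure likeness. Ribosomal protein genes lay lower in the striatum for 29 of 30 (-0.39, camera adjusted p = 0.00057, 0.719 estimated), and the astrocyte list had a median of 0.03 (camera adjusted p = 0.756).

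The 4 interferon receptor genes differed in how many counts KO cells kept, and the labels do not say which chains were targeted. Ifngr1 (10:19591949-19610229) gave 0 counts in 79 KO vSVZ astrocytes [0 to 0.312 CPM] and 27.9 CPM [25.5 to 30.5] in TiCY, at least 110-fold lower; in striatal astrocytes it gave 0.457 CPM [0.0553 to 1.65] from 2 counts, against 34.2 [31.4 to 37.2]. Ifnar1 (16:91485238-91507441) kept 9.22 CPM [7.57 to 11.1] against 47.1 [43.9 to 50.4] in vSVZ astrocytes, and 8.90 [6.33 to 12.2] against 61.3 [57.6 to 65.3] in striatal astrocytes. Ifnar2 and Ifngr2, the partner chains on the same chromosome, kept 63.7 CPM [59.3 to 68.5] against 37.2 [34.4 to 40.2] and 10.7 [8.95 to 12.8] against 17.9 [15.95 to 19.996] in vSVZ astrocytes. In naive striatal astrocytes Ifnar2 went the other way and was lower in KO than in TiCY. Counts per gene cannot tell where the remaining reads lie relative to a deleted part. Interferon response genes had a median log2 ratio near 0 in naive cells: 0.01 [-0.12 to 0.12] in vSVZ astrocytes, 0.15 [-0.07 to 0.30] in qNSC2 and 0.18 [-0.13 to 0.40] in striatal astrocytes.

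**Figure D3:**
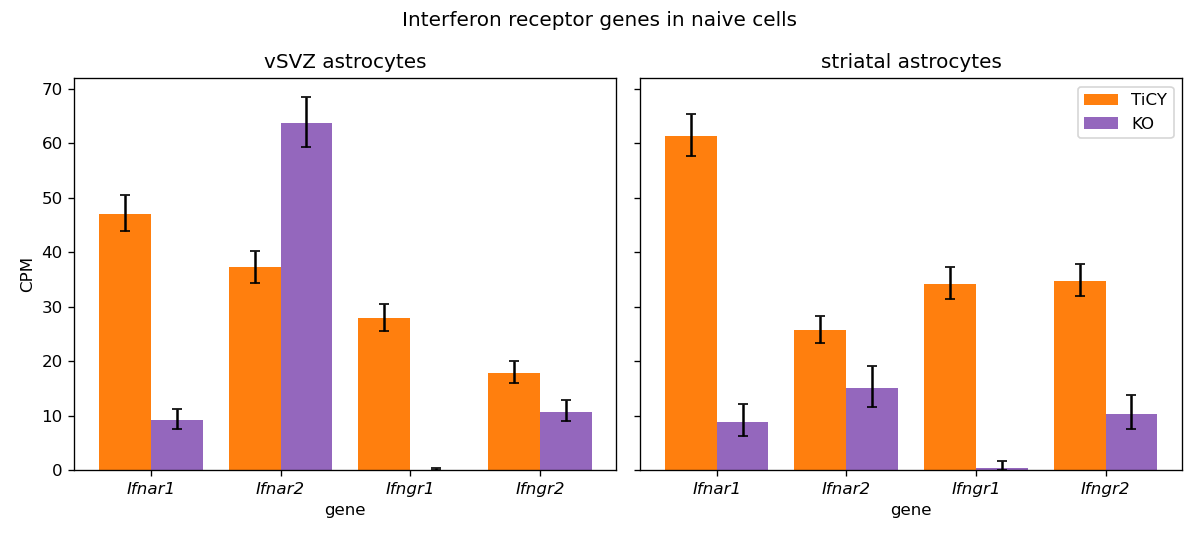
CPM of the 4 interferon receptor genes (x) in naive TiCY and KO astrocytes of the vSVZ and striatum, on an axis from 0 (y). Bars are values of 1 replicate each, with exact Poisson intervals, such as 27.9 against 0 CPM for Ifngr1 in the vSVZ.

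Sterol genes and Pde10a were among the differences between naive KO and TiCY astrocytes. The 2 libraries also parted by cluster: of 3 astrocyte-like clusters with naive vSVZ cells, 1 held 18 KO and 91 TiCY cells and another 60 KO and 15 TiCY cells. Stard4, a sterol carrier, was at 88.1 CPM [82.8 to 93.6] in KO against 19.5 [17.5 to 21.7] in vSVZ astrocytes, and at 121 [111 to 132] against 14.9 [12.99 to 16.9] in the striatum. Cholesterol synthesis genes lay higher in KO for 15 of 17 in the vSVZ (median log2 ratio 0.49 [0.43 to 0.58], above 99.9% of random lists) and for 14 of 17 in the striatum (0.47 [0.34 to 0.68]). Pde10a, a phosphodiesterase of striatal neurons, was at 5.24 CPM [4.02 to 6.72] in KO against 322 [314 to 331] in the vSVZ. With 1 replicate per genotype, and the background of naive KO cells left open, these differences were not tested.

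The TiCY vSVZ sort held far more neuroblast and reactive gene counts 2 d after ischemia than without it. Gfap, the intermediate filament of reactive astrocytes (11:102887336-102900912), was at 1294 CPM [1282 to 1306] 2 d after ischemia against 60.3 [57.5 to 63.2] in naive cells, and Serpina3n, a secreted protease inhibitor, at 213 [208 to 218] against 3.68 [3.01 to 4.45]. Socs3, the feedback inhibitor of STAT3, was at 191 [187 to 196] against 4.97 [4.19 to 5.86]. S1pr1, a lipid receptor of quiescent astrocytes, was at 35.3 [33.3 to 37.3] against 791 [781 to 802], and the noncoding Rmst at 22.01 [20.5 to 23.6] against 583 [574 to 592]. Reactive genes lay higher for 21 of 22 (median log2 ratio 2.44), neuroblast genes for 19 of 20 (2.10 [2.07 to 2.16]) and ribosomal protein genes for 30 of 30 (1.41 [1.37 to 1.42]). Astrocyte genes lay lower for 18 of 18 (-2.55 [-2.60 to -2.52]) and fatty acid oxidation genes for 19 of 19 (-1.32 [-1.35 to -1.25]). At 21 d Gfap was at 109 [105 to 114] and the reactive median at 0.81 [0.69 to 0.87], and at 0.19 without the 5% of cells with each gene's highest shares. Each arm was 1 replicate, so time after ischemia and library could not be told apart.

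In the TiCY striatum the ratios of reactive genes were larger. Flnc, an actin crosslinker of stressed cells (6:29433256-29461883), was at 586 CPM [579 to 592] 2 d after ischemia with 0 counts in naive cells, at least 3141-fold higher, and its highest cell held 9.23% of its counts. Osmr, the oncostatin M receptor, was at 339 [334 to 344] against 3.98 [3.06 to 5.08], Anxa2 at 1065 [1056 to 1075] against 9.32 [7.89 to 10.9], and Gfap at 1915 [1903 to 1927] against 32.2 [29.5 to 35.2]. Of the 8 genes with the highest ratios, 6 drew 86.2% to 99.4% of their counts from 1 cell, Aknad1 among them. Hapln1, which stabilises the matrix around neurons, was at 7.57 [6.83 to 8.37] against 217 [209 to 224]. Reactive genes lay higher for 22 of 22 (median log2 ratio 3.92 [3.86 to 4.02]), immediate early genes for 17 of 18 (2.60) and interferon response genes for 19 of 28 (1.32 [1.19 to 1.39], and 0.81 without the 5% of cells with each gene's highest shares), Ifitm3 among them at 173 CPM [169 to 176] against 7.89 [6.58 to 9.39]. At 21 d the neuroblast list led (16 of 16, 2.76 [2.68 to 2.84]), although 5 of 79 cells were neuroblast-like (6.33% [2.09 to 14.2]), and interferon response was at 0.22 [0.07 to 0.27]. Cit, a kinase of cytokinesis, was then at 232 [224 to 241] against 1.80 [1.21 to 2.59], and Sox4, a factor of young neurons, at 173 [166 to 180] against 8.39 [7.03 to 9.93].

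KO cells also had more reactive gene counts at 2 d. In the KO striatal sort 2 d after ischemia Vim, the filament partner of Gfap, was at 215 CPM [206 to 224] against 2.28 [1.10 to 4.20] in KO naive cells, Gfap at 534 [520 to 548] against 26.0 [21.5 to 31.3], and Egr1, an immediate early factor, at 474 [461 to 487] against 0, at least 692-fold. Reactive genes lay higher for 16 of 18 (median log2 ratio 2.71 [2.58 to 2.84]) and neuroblast genes for 17 of 18 (3.08 [2.92 to 3.24]). The neuroblast median was 3.70 [3.39 to 3.79] for the portion labelled KO1 and 0.95 [0.64 to 1.37] for KO2, where 6 of 61 and 0 of 53 cells were neuroblast-like. Interferon response genes had a median of -0.40 [-0.50 to -0.19], 8 of 18 higher, and of 0.02 without the 5% of cells with each gene's highest shares; Stat2 was at 64.1 [59.4 to 69.1] against 91.6 [82.8 to 101]. In the KO vSVZ sort the reactive median was 1.86 [1.78 to 1.93], the neuroblast median 1.61 [1.56 to 1.70] and the interferon median -0.18 [-0.28 to -0.01] (0.20 without those cells), yet Ifitm3 was at 149 [145 to 153] against 22.8 [20.7 to 24.9]. The difference between genotypes was not tested.

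**Figure D4:**
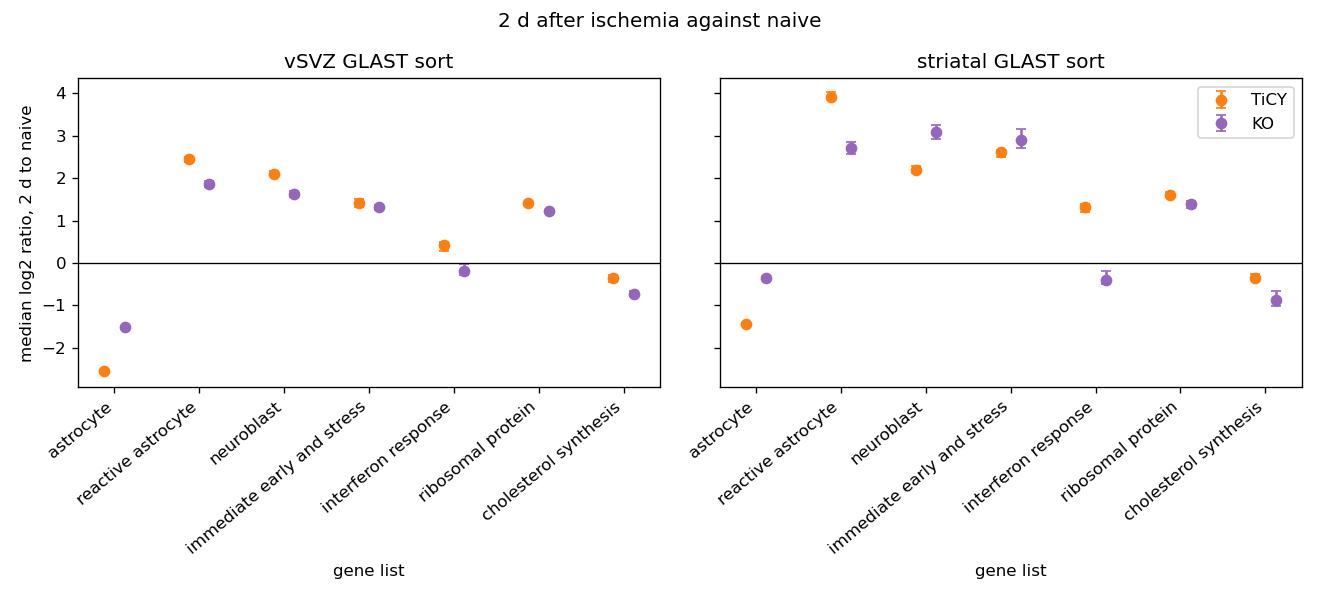
Median log2 ratio of 2 d post-ischemia to naive (y) for 7 gene lists (x) in TiCY and KO cells, with 1 panel for the vSVZ sort and 1 for the striatal sort. Points carry counting intervals, such as 1.32 in TiCY and -0.40 in KO for interferon response genes in the striatum.

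By labelled type, KO stem cells and astrocytes held more counts of the same genes at 2 d. In qNSC2 Serpina3n was at 232 CPM [222 to 242] against 0, at least 380-fold, S1pr3, a lipid receptor of reactive glia, at 213 [204 to 223] against 0, at least 350-fold, and Gfap at 3916 [3876 to 3956] against 163 [152 to 174]. In vSVZ astrocytes Gfap was at 1255 [1226 to 1284] against 61.4 [57.0 to 66.01], while Sox9, an astrocyte fate factor, was at 61.2 [54.9 to 67.9] against 619 [605 to 634]. Reactive genes lay higher for 19 of 19 in qNSC2 (median log2 ratio 2.25 [2.15 to 2.37]), 10 of 10 in vSVZ astrocytes (1.66 [1.57 to 1.82]) and 9 of 11 in striatal astrocytes (1.59 [1.42 to 1.82]). Cholesterol synthesis genes lay lower for 12 of 17 in vSVZ astrocytes (-0.91 [-1.02 to -0.75]) and 14 of 17 in striatal astrocytes (-0.77 [-0.97 to -0.64]); Nsdhl, a sterol dehydrogenase, was at 29.5 [25.2 to 34.3] against 393 [382 to 405] in the former. The aNSC, TAP and neuroblast groups of naive KO held 7 to 9 cells each. In the striatum 66 of 114 KO cells at 2 d fell in an astrocyte-like cluster without a naive cell, so these ratios do not part library from state.

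With both genotypes as replicates, 2 d was tested against naive in the striatal sort; the same fit for the vSVZ sort was not run. Nes, a filament of neural progenitors (3:87971078-87980451), averaged 176 ± 160 CPM against 0, at least 1146-fold (edgeR adjusted p = 2.2e-18, higher in 2 of 2 genotypes). Cd44, a hyaluronan receptor, averaged 158 ± 21.8 against 2.55 ± 2.93 CPM (6.33 ± 0.90, edgeR adjusted p = 1.3e-09, higher in 2 of 2). Stmn2 (3:8509360-8561606) averaged 129 ± 10.4 against 0.249 CPM (8.93 ± 1.02, edgeR adjusted p = 9.4e-15, higher in 2 of 2), and Dlx1, a homeobox gene of interneurons, 74.7 ± 50.4 against 0.065 CPM (9.08 ± 1.11, edgeR adjusted p = 5.6e-13, higher in 2 of 2). Apln, the ligand of the apelin receptor, fell from 216 ± 54.5 to 26.9 ± 23.4 CPM (-3.32 ± 0.78, edgeR adjusted p = 0.002, lower in 2 of 2), and Hapln1 from 237 ± 14.6 to 38.8 ± 44.0 CPM (-3.35 ± 0.80, edgeR adjusted p = 0.0025, lower in 2 of 2). edgeR called 515 of 22409 genes, 449 higher and 66 lower, with 1 residual degree of freedom and a spread taken entirely from the trend over genes (infinite prior degrees of freedom); limma with equal weights called 44. They held 19 of 24 reactive genes (21 over the list alone, median 6.11), 11 of 20 neuroblast genes, 11 of 19 immediate early genes and 1 of 38 interferon response genes (median 0.87, camera adjusted p = 0.2). Reactive genes had camera adjusted p = 1.1e-23, and no list held with an estimated correlation (lowest 0.643). Without the 5% of cells with each gene's highest shares, edgeR called 313 genes, 203 higher and 110 lower; among genes detected in at least 20% of cells it called 1, and neither Nes, Cd44, Apln nor Hapln1. Stmn2 and Dlx1 gave no value among genes detected in at least 20% of cells, and were still called with KO2 alone in place of the KO sum. Neuroblast-like cells were 5 of 122 in TiCY and 6 of 114 in KO at 2 d, so the calls of Stmn2 and Dlx1 may rest on few cells.

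Clusters named by marker scores put numbers on these shifts. The naming rule was set after a first clustering had been seen. Neuroblast-like cells made up 7.98% [4.53 to 12.8] of the naive TiCY vSVZ sort (15 of 188 cells), 59.1% [51.4 to 66.4] at 2 d (104 of 176) and 6.45% [3.14 to 11.5] at 21 d (10 of 155). In KO they were 7.46% [3.64 to 13.3] of naive cells (10 of 134) and 34.6% [28.5 to 41.2] at 2 d (79 of 228). The class pools 2 clusters: naive TiCY had 14 cells in 1 and 1 in the other, TiCY 2 d 9 and 95, and the latter cluster drew 95 of its 134 cells from that sort. In the striatum reactive-like cells were 0 of 131 in naive TiCY, which allows a share of up to 2.29% by 3 counts of the total (exact upper limit 2.78%), 74.6% [65.9 to 82.0] at 2 d (91 of 122) and 1.27% at 21 d (1 of 79). In KO they were 0 of 35, which allows up to 8.57% (exact limit 10.003%), and 5.26% [1.96 to 11.1] at 2 d (6 of 114). That cluster drew 91 of its 110 cells from TiCY 2 d striatum and may mark that library as much as a cell state. Its 10 top genes held no reactive marker. They included Adam2, Tsga10ip, Kif28, Aknad1 and Ankdd1a, each with most of its counts in 1 cell of that sort. At resolution 2 the reactive-like share of the sort was 39.3%, and a cluster of 56 cells led by these genes was named endothelial-like. An unnamed cluster led by Thbs4, with 116 cells labelled qNSC2, held 20.2%, 10.2%, 19.4%, 22.4% and 26.8% of the vSVZ sorts in the same order of arms. At 50000 counts per cell, Gfap was found in 18.9% of naive and 71.3% of 2 d TiCY striatal cells (22.1% and 80.3% without thinning), with 25 and 0 cells left out for lower depth. In KO it was found in 27.6% of naive and 81.1% of 2 d striatal cells, with 6 and 24 left out. Vim was in 73.3% of KO and 70.5% of TiCY striatal cells at 2 d. Osmr, Cd44, Serpina3n, Flnc and Tnfrsf12a were in fewer KO than TiCY cells there, such as Osmr in 17.8% against 65.6%.

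**Figure D5:**
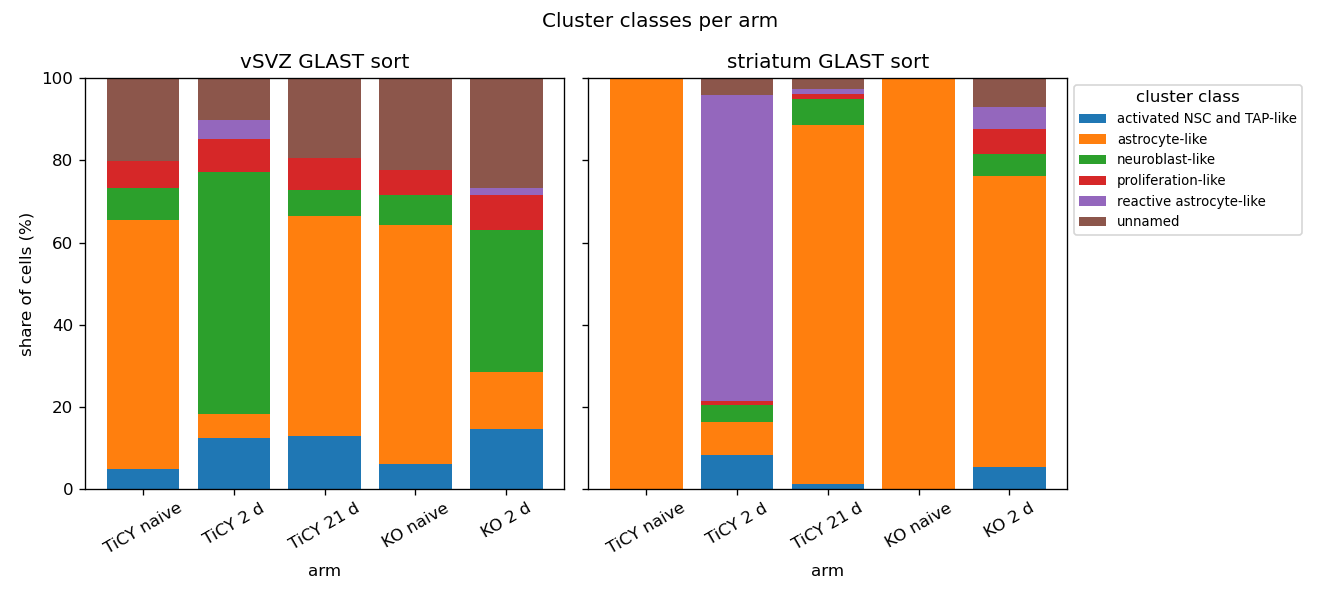
Share of cells per cluster class, in percent from 0 to 100 (y), for each arm of the vSVZ and striatal sorts (x). Bars are stacked by class, such as 59.1% neuroblast-like for TiCY vSVZ at 2 d.

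Cells labelled as neurogenic in the KO striatum had higher summed counts of neuroblast genes and lower ones of astrocyte genes; where they came from was not tested. By cluster, of 33 cells with this label in both genotypes 6 were neuroblast-like, 12 activated NSC and TAP-like, 7 proliferation-like and 8 in the unnamed cluster led by Thbs4. They were 23.7% [16.2 to 32.6] of that sort at 2 d (27 of 114), 23 of 61 in the portion labelled KO1 and 4 of 53 in KO2. Against striatal astrocytes of the same replicate, Stmn2 was at 602 CPM [573 to 633] against 0.40 [0.0824 to 1.17] from 3 counts, Gad2, which makes GABA, at 445 [420 to 471] against 0.932 [0.375 to 1.92], and Dlx1 at 483 [457 to 510] against 1.47 [0.731 to 2.62]. Il33 had 0 counts [0 to 1.40 CPM] against 280 [268 to 292], at least 247-fold lower. Neuroblast genes lay higher for 19 of 20 (median log2 ratio 4.39 [4.25 to 4.48]), proliferation genes for 20 of 20 (3.04 [2.92 to 3.24]) and astrocyte genes lower for 18 of 18 (-2.78 [-2.89 to -2.69]). The 6 cells with this label in TiCY had a neuroblast median of -2.46 [-2.57 to -2.38] against other striatal cells, of -0.77 without the 5% of cells with each gene's highest shares, and of -4.47 and -1.22 with priors of 1 and 20 CPM. Those 109 other cells included the 5 neuroblast-like cells of the TiCY sort. None of the KO striatal astrocytes was neuroblast-like, so the KO and TiCY medians had unlike comparators. Labels may rest on the transcriptome, so these values describe the labels rather than test them. The 5 reactive-labelled KO cells had Cd44 at 2336 [2214 to 2463] against 35.4 [31.3 to 39.9] and Hes5, a Notch target, at 0 [0 to 6.27] against 988 [966 to 1011]. Reactive genes lay higher in them for 23 of 23 (4.52 [4.37 to 4.67]) against striatal astrocytes. The 7 TiCY cells with that label had a median of -0.26, but against 109 striatal cells labelled only as astrocytes and NSC lineage cells. Of that whole TiCY sort 91 of 122 cells were reactive-like, so this median does not show a lack of reactive genes.

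Cortical and striatal astrocytes of replicate pL, from mice with the TCF-Lef reporter, differed in regional genes. Of the 32 cortical cells 31 came from a sort named GFP+, as did all 33 striatal ones. They need not stand for all astrocytes of a region. Crym, a thyroid hormone binder of striatal astrocytes (7:120186380-120202111), had 0 counts [0 to 0.76 CPM] in the cortex against 802 [778 to 826] in the striatum, at least 1298-fold. Zic2, a patterning factor, was at 178 [166 to 190] in the cortex against 7.06, and Egr1 at 101 [92.4 to 110] against 0, at least 181-fold. Forebrain patterning genes had a median log2 ratio of 0.67 [0.58 to 0.76], 6 of 10 higher, and immediate early genes 1.15 [1.02 to 1.44], 12 of 12 higher. The 32 and 33 cells came from 1 replicate.

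Cells of the olfactory bulb had higher counts of mature neuron genes than vSVZ neuroblasts; with 1 bulb replicate, maturation is not parted from tissue, sort or library. Calb2, the calcium buffer of periglomerular neurons (8:110137502-110168210), was at 1703 CPM [1676 to 1730] in the bulb with 0 counts in 79 vSVZ neuroblasts, at least 23527-fold higher. Gria1, an AMPA receptor subunit, was at 393 [380 to 406] against a mean of 0.496 [0.284 to 0.767] over 4 replicates, with log2 ratios of 6.03 to 6.31. Top2a, which untangles DNA at mitosis, was at 6.71 [5.14 to 8.60] against 461 [447 to 476], with log2 ratios of -5.98 to -3.92, and -5.76 and -5.98 against pC and pD of the same library set. Mature neuron genes lay higher for 7 of 7 (median log2 ratio 2.23 [2.09 to 2.37]), oxidative phosphorylation genes for 20 of 21 (0.88 [0.83 to 0.94]) and glycolysis genes for 13 of 15 (1.07 [1.02 to 1.17]). Proliferation genes lay lower for 19 of 20 (-2.28 [-2.35 to -2.18]).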

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

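The comparison of the 101 cells held by the ischemia table alone was chosen after the data were seen; the other rules here were set beforehand.

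Interferon response genes had medians on opposite sides of 0 in TiCY and KO 2 d after ischemia, but not without the 5% of cells with each gene's highest shares. In the striatal sort the list had a median log2 ratio of 1.32 in TiCY (28 members) and -0.40 in KO (18 members), and in the vSVZ sort 0.41 and -0.18; without those cells the KO values were 0.02 and 0.20. Each genotype was 1 replicate per time, so the difference was not tested, and library, depth and genotype cannot be told apart. The striatal TiCY value was 0.81 without those cells and 0.54 with a prior of 20 CPM, and the vSVZ one was 0.12 with equal weight of cells. The receptor list itself had medians of -0.76 in TiCY and 0.93 in KO in the striatum; in KO Ifnar2 was at 97.2 CPM at 2 d against 15.1 and Ifngr1 at 2.14 against 0.457.

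Other lists also had opposite medians in the 2 genotypes. In the striatum oligodendrocyte genes had a median of 0.37 in TiCY and -0.88 in KO, oligodendrocyte precursor genes 0.82 and -0.084, and glycolysis genes -0.59 and 0.14. Forebrain patterning genes had -0.13 in TiCY and 1.03 in KO in the striatum, and 0.23 and -0.26 in the vSVZ. Without those cells the TiCY medians were -0.080 for oligodendrocyte genes in the striatum and -0.18 for forebrain genes in the vSVZ, on the same side as KO. Neurogenic-labelled cells, which carry Dlx genes, made up 27 of the 114 KO cells in the striatum. None of these differences was tested.

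Among the genes named in tests, 27 groups of 4 or more replicates were searched for a value far from the others, and 4 had one; chance gives about 1 in 20 groups. For Olig1 in qNSC2, replicate pE was at 0.154 CPM and the others at 0, a gap of 1.0 of the range. For Thbs4 and for Axl in neuroblasts, pB was at 0.0395 CPM and the others at 0, a gap of 1.0 each. These 3 are a few counts next to none. Acsl6 in qNSC1 was at 789 CPM in pD and 1437 in the nearest replicate, a gap of 0.770 of the range; without pD its fall in oligodendrocytes was still called.

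The 101 cells that the ischemia table holds alone were mostly oligodendrocyte-like: 89.1% had an Mbp count, against 20.5% of the 513 cells in both tables, with a median of 1470.0 counts. Mog was found in 84.2% of them and Gja1 in 5.94%. They entered no comparison.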

How the results depend on the processing

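The fits within a library set or with it as a block, those among genes detected in at least 20% of cells and those without the 5% of cells with each gene's highest shares were chosen after the data were seen. No value below changed direction where its interval or test had excluded 0, except that without those 5% the interferon medians of KO sorts at 2 d went from -0.40 to 0.02 in the striatum and from -0.18 to 0.20 in the vSVZ. As given above, the TiCY medians at 2 d of oligodendrocyte genes in the striatum and of forebrain patterning genes in the vSVZ also changed sign under that setting. Counts of called genes depended on the tool: DESeq2 called more in each comparison, and the self-test recovered few changes under 16-fold. The cause of a difference between settings was not tested unless fewer samples, cells or genes were used. Some fits leave a group with 2 sums or 1, as for aNSC and TAP within pA, pB and pE, where the lone sum was assumed to vary like the other groups; for naive pM and pJ leave-one-out fits could not be fitted for want of residual degrees of freedom.

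With DESeq2 the calls were 286 for qNSC2 against qNSC1 (12 with edgeR), 974 for aNSC against qNSC2 (29), 171 for TAP against aNSC (0), 309 for neuroblasts against TAP (14), 2495 for oligodendrocytes against qNSC1 (1636), 2979 for the NB sort (1690), 1883 for OLIGO (875), 467 for ASTRO (13), 9 for striatal against vSVZ astrocytes (0), 107 for qNSC2 against vSVZ astrocytes (2) and 1070 for 2 d against naive in the striatum (515). With equal weight of cells and limma trend they were 271 for qNSC2 against qNSC1, 587 for aNSC, 9 for TAP, 69 for neuroblasts, 1337 for OLIGO, 60 for ASTRO, 4 for qNSC2 against vSVZ astrocytes and 44 for 2 d in the striatum. Without the gene filter they were 102 for ASTRO, 8 for striatal and 69 for qNSC2 against vSVZ astrocytes. The other counts under these settings stayed within 1.5 times.

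Letters pair the sums, and with the replicate block the calls were 60 for qNSC2 against qNSC1, 312 for aNSC, 18 for TAP, 2755 for NB and 38 for ASTRO; the block changed the calls of Dcx, Sp8 and Csrnp3 and no other call of a gene followed here. With only the 2 groups compared, which leaves fewer sums to estimate spread, 0 were called for aNSC, neuroblasts and ASTRO, and 12 for qNSC2 against vSVZ astrocytes, without Ccnd2 and Dscaml1. At least 5 cells per sum gave 0 for aNSC (fewer sums) and 8 higher and 1 lower for qNSC2 against qNSC1 (5 and 7), and at least 1 cell gave 24 for TAP and 9 for neuroblasts. Naive pM and pJ in place of WT gave 8 for aNSC, 5 for TAP and 656 for neuroblasts, 89 higher and 567 lower. Within pA, pB and pE the calls were 22 for qNSC2 against qNSC1, 320 for aNSC, 10 for TAP and 353 for neuroblasts; within pC and pD 0, 0, 0 and 0 in the same order and 186 for oligodendrocytes. With the library set as a block they were 31, 162, 6 and 42 in the order of the first 4.

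Leaving out 1 replicate moved most counts. For qNSC2 against qNSC1 the range was 0 to 25 (0 without pA or pB, 1 without pC, 4 without pE, 25 without pD), for aNSC 0 to 218 (1 without pA or pB, 0 without pC or pE, 218 without pD), for TAP 0 to 19 (19 without pD, otherwise 0) and for neuroblasts 0 to 84 (1 without pA, 0 without pB, 6 without pC, 3 without pE, 84 without pD). For oligodendrocytes it was 800 to 1950 (885 without pA, 847 without pB, 800 without pC), for NB 369 to 1335 (481 without pA, 369 without pB), for OLIGO 273 to 487 (273 without pA, all lower, 333 without pB, 487 without pC) and for ASTRO 0 to 73 (0 without pA or pB, 73 without pC, 12 higher and 61 lower). The cause of the rises without pD, and for ASTRO without pC, was not tested. For 2 d in the striatum, time alone without a genotype term gave 284, without the 21 d sum 343, only genes detected in at least 20% of cells 1, and without the 5% of cells 313.

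Medians of lists moved with the prior. With 1 CPM and then 20 CPM the reactive list at 2 d was 2.01 and 1.34 in KO vSVZ astrocytes (1.66 with 5), 3.42 and 1.54 in KO qNSC2 (2.25), 2.05 and 1.01 in KO striatal astrocytes (1.59), 3.07 and 1.245 in the TiCY vSVZ sort (2.44) and 5.04 and 2.67 in the TiCY striatal sort (3.92). At 21 d it was 0.92 and 0.52 in the vSVZ (0.81), and 0.54 with 20 in the striatum (0.72). The interferon list was 0.50 and 0.18 in the TiCY vSVZ at 2 d (0.41), 0.40 and 0.15 at 21 d (0.32), and 1.65 and 0.54 in the striatum at 2 d (1.32). For neurogenic-labelled cells the neuroblast list was 5.73 and 3.26 in KO (4.39) and -4.47 and -1.22 in TiCY (-2.46), for reactive-labelled KO cells the reactive list 4.79 and 3.18 (4.52), and for the bulb the mature neuron list 1.77 with 20 (2.23).

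With equal weight of cells the reactive list was 1.06 in KO vSVZ astrocytes, 1.87 in KO qNSC2, 1.85 in KO striatal astrocytes, 2.21 in the TiCY vSVZ sort at 2 d, 3.99 in reactive-labelled KO and -0.14 in TiCY cells. The interferon list was 0.12 in the TiCY vSVZ at 2 d, 0.21 at 21 d and -0.17 in naive KO against TiCY qNSC2, whose interval of 0.15 spans 0; the mature neuron list of the bulb was 1.98. Without the 5% of cells with each gene's highest shares the reactive list was 2.03, 2.11 and 1.99 in the 3 KO types in the same order, 1.69 in the TiCY vSVZ at 2 d, 0.19 at 21 d, 4.40 in the striatum, 5.01 in reactive-labelled KO and -0.053 in TiCY cells. The interferon list was then 0.049 in the vSVZ at 21 d, 0.81 in the striatum at 2 d and 0.0497 at 21 d, so the 21 d values rest on few cells. The neuroblast list was 4.81 in neurogenic-labelled KO and -0.77 in TiCY cells, the forebrain list of the cortex 0.41 and the mature neuron list of the bulb 1.965. No cell had under 1000 genes, so that setting moved nothing.

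Reactive-like cells of the TiCY striatum at 2 d were 39.3% at resolution 2 (74.6% at 1), and at 21 d 0% at resolution 0.5 and with another seed (1.27%). Neuroblast-like shares were equal at these settings. Of 95 gene values followed, tested ones kept their side of the threshold in 364 fits, lost it in 147 and gained it in 8, and none reversed. Ratios without a test lay beyond their interval in 151 settings and within it in 104. Most of these intervals were of the ratio with no CPM added, while the ratios given have 5 CPM added. A given ratio can thus lie outside its own interval, so these 2 counts do not measure stability. Calls lost numbered 19 without pA, 19 without pB, 16 without pC, 12 without pE and 1 without pD, 15 within pC and pD, 14 with only the groups compared, 12 with at least 5 cells per sum, 8 with pM and pJ and 7 with equal weight. They numbered 6 of 6 among genes detected in at least 20% of cells, 4 within pA, pB and pE, 4 with at least 1 cell per sum, 3 with time only, 2 without the 21 d sum, 2 without the gene filter, and 1 each with KO2 for the KO sum, with the block and without the 5% of cells.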

Other observations

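Of the tests in this part, those on single cells, on the rise in both genotypes, on free RNA and on the genotype or untreated state were chosen after the results were seen; the splits and the tests on whole myeloid cells, fewer astrocytes, doublets and depth were not.

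Of the DNA methylation list, Gadd45b and Gadd45g were called higher 2 d after ischemia, while the list did not hold with an estimated correlation (camera adjusted p = 0.643). With both genotypes as replicates of the striatal sort, Gadd45b (99.7 ± 111 CPM at 2 d against 1.35 ± 1.58, log2 fold change 6.25 ± 1.02, edgeR adjusted p = 3.2e-07, higher in 2 of 2) and Gadd45g (387 ± 299 against 63.1 ± 32.2, 2.46 ± 0.72, edgeR adjusted p = 0.032, higher in 2 of 2) rose. Neither was called by limma with equal weights (adjusted p = 0.0563 for Gadd45b and 0.0840 for Gadd45g), nor Gadd45g among genes detected in at least 20% of cells (0.273), where Gadd45b gave no value. In TiCY striatum the de novo methyltransferase Dnmt3a was at 107 CPM [104 to 110.0] against 317 [308 to 326]. The list had median log2 ratios at 2 d of 1.06 [0.97 to 1.10] in TiCY and 1.44 [1.24 to 1.60] in KO striatum, and 0.63 [0.56 to 0.67] and 0.75 [0.65 to 0.81] in the vSVZ. At 21 d it was at 0.17 [0.12 to 0.23] in the striatum and 0.09 [-0.03 to 0.21] in the vSVZ.

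Sterol genes were followed in sorts and in labelled types after ischemia. Nsdhl fell in the striatal sort (64.1 ± 24.1 CPM at 2 d against 362 ± 75.4, -2.54 ± 0.73, edgeR adjusted p = 0.028, 0.0648 by limma with equal weights and 0.292 among genes detected in at least 20% of cells, lower in 2 of 2) and was at 25.7 CPM [24.0 to 27.4] against 339 [332 to 346] in the TiCY vSVZ sort, whose astrocyte-like cells were 60.6% in naive and 5.68% at 2 d. In KO qNSC2 the cholesterol list had a median of 0.27 [0.15 to 0.47], 12 of 17 higher, against -0.91 in KO vSVZ astrocytes, a difference that was not tested, and Fdps was at 279 CPM [269 to 290.2] at 2 d against 24.8 [20.6 to 29.6]. In the same cells Ifitm3 was at 383 [370.4 to 395] against 40.6 [35.2 to 46.7]. The portions labelled KO1 and KO2 of the KO striatal sort differed: against KO2, KO1 had a neuroblast median of 2.26 [2.15 to 2.44], proliferation 1.71 [1.495 to 1.86] and reactive astrocyte -1.14 [-1.42 to -0.95].

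The genes with the highest ratios in the TiCY striatum at 2 d came in 2 kinds. For 6 of 8, 1 cell held 86.2% to 99.4% of the counts, and without the 5% of cells with the highest shares their median log2 ratio was 1.65 against 7.31. A rise in both genotypes stays open for these 6: their median in KO was 0.14 (-0.74 to 1.53), with 4 of them under 5 CPM at both times, too near the floor to tell. Flnc and Tnfrsf12a kept ratios of 6.97 or more without those cells (6.69 or more with them), which excludes single cells for this pair. In this sort 19 cells had over 10% of counts in 1 gene, 18 different genes, with 33.5% at most; what put so many reads on 1 gene may lie in the library and was not tested, while Flnc and Tnfrsf12a may belong to the injury response.

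Naive TiCY cells held neutrophil and macrophage RNA across types, with S100a8 at 173 CPM and Lyz2 at 179 in vSVZ astrocytes. Whole myeloid cells or doublets were excluded: the 16 of 333 cells with the highest shares held 19.8% of the S100a8, S100a9 and Lyz2 counts, and 90.7% of cells had a count. Free RNA in the wells may be the source, since ratios between these genes differed at most 1.57-fold between types and 61.1% to 76.9% of cells per type had S100a9. The genotype or untreated state stays open, as there was 1 replicate of naive TiCY cells. CD45 antibody was part of the stain; a gate against it would remove whole cells and not free RNA, but how it was gated is not given in the sources used here.

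The larger neuroblast-like share of the TiCY vSVZ sort at 2 d was set against 3 technical explanations. Of cells that were not astrocyte-like, 62.7% were neuroblast-like at 2 d against 20.3% in naive (lower limit 54.8, upper limit 31.2). Fewer astrocytes alone thus did not account for the larger share beyond counting error. Each arm was 1 replicate, so spread between libraries was not measured. For doublets, the median astrocyte share of counts in neuroblast-like cells at 2 d was 0.423% of that in naive astrocyte-like cells. The typical neuroblast-like cell was thus not a doublet with an astrocyte. These cells were chosen by clusters of the same counts, and a median can miss a minority, so doublets were not excluded for the rest. Depth was excluded: at 50000 counts per cell 69.7% against 8.47% of cells had Dcx, a ratio of 8.23 (69.9% and 10.6% without thinning, 24 and 11 cells left out). More neurogenesis, fewer GLAST-positive astrocytes together with it, or a wider sort gate in that library may each remain; neuroblast-like cells per activated or proliferating cell were 0.714 in naive, 2.89 at 2 d and 0.313 at 21 d, and 0.625 and 1.52 in KO.

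Other splits of the same sums were set beside the real ones. For qNSC2 against qNSC1, 1 of 40 splits gave as many genes (12, highest other 1), and for oligodendrocytes against qNSC1 1 of 40 (1636, highest other 0). That split was the real one in both. These splits ignore the pairing by letter, so they do not settle whether chance is excluded. Of the splits that part as many pairs as the real one there were 4 others (highest 1) and 7 others (highest 0), too few for a share under 0.05. The labels may rest on these transcriptomes, which favours the real split, and without pA or pB the 12 calls fell to 0. For aNSC against qNSC2 2 of 35 did (29, highest other 51) and for neuroblasts against TAP 4 of 35 (14, highest other 100), so chance could not be excluded. The splits with 51 and 100 genes moved 1 sum of pD to the other side, qNSC2 and neuroblasts in turn, which points to a structure of the samples. The letters pair the sums, and those splits left the pD pair on 1 side; of the 11 other splits in each that part as many pairs as the real one, none called a gene, though 11 are also too few for a share under 0.05. For TAP against aNSC there were 10 splits, too few for a share under 0.05 (10 with as many, real 0, highest other 2), as for the NB (1 of 10, 1690 and 0), OLIGO (1 of 10, 875 and 0) and ASTRO sorts (1 of 10, 13 and 0). By edgeR TAP against aNSC had 937 genes at unadjusted p below 0.05, and DESeq2 called 171.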
